A study of Mus musculus with 20 samples.

How the data were processed

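Polyadenylated RNA from mouse ovary was sequenced on a DNBSEQ instrument in 20 libraries, 5 in each of the groups Control, Model, LNPIFN-Y and ptLNPIFN-Y. Per the submitters' processing notes, reads were aligned to GRCm38.p6 with HISAT2, transcripts were assembled with StringTie, expression was estimated with RSEM and differential expression was computed with DESeq2, with no versions stated. The deposited table holds expected counts (RSEM estimates), in which 9.85% of values carry decimals. Strandedness is not stated. The table has 20960 genes, of which 20742 are protein-coding and 1515 have no count in any library. Of these, 1 row had been emptied for this work and was not used here. Symbols of 26 genes had been turned into dates and were restored by Entrez ID from a RefSeq gene table. That table matched 20899 gene IDs and left 61 unmatched, and start and end positions were equal in 99.55% of rows.

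Expected counts, as deposited, were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 15723 tested. Library sizes were scaled by TMM, dispersions were estimated, and 1 quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all libraries, with 4 main and 2 secondary contrasts and 16 residual degrees of freedom at the least. The common biological coefficient of variation was 0.439. P values were adjusted by Benjamini and Hochberg over all tested genes, and an adjusted p under 0.05 counted as past the test. The SE of a log2 fold change is the fold change divided by the root of its F statistic. CPM values are edgeR counts scaled to the TMM-adjusted library sizes, and log2 CPM uses a prior count of 2. Total counts per library lay between 16496793 and 17218043. On counts simulated for the 4 main contrasts, the test found 54%, 57%, 50% and 51% of 100 genes changed 2-fold. Of 100 genes changed 4-fold it found 79%, 80%, 86% and 67%, and 5.6%, 5.6%, 5.1% and 3.6% of calls were false. Changes were placed only in genes above a mean of 1 CPM, and each gene was drawn independently. Low-count genes and variation shared across genes are therefore not covered.

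The groups, contrasts, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule named, among others, Ifng, Irf1, Cxcl9, Cd274, Cd8a, Mki67 and Msln in every main contrast; some genes it names are not used here. It added the 5 genes with the highest and the 5 with the lowest log2 fold change among those past the test with a mean log2 CPM of at least 1 and no overlap between the libraries of the 2 groups, without clone-type symbols and receptor segments. It also added, for at most 8 lists past the camera test by smallest p (or the 3 with the smallest p where fewer passed), the 2 members with the smallest p. Genes outside the rule are marked where they are named.

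There were 36 lists of marker genes with 804 entries, of which 29 are absent from the table. The 35 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. P values were adjusted over the lists within a contrast. Members were counted as risen or fallen by their adjusted p over all genes, and separately adjusted over the list alone. A list mean is the mean log2 CPM of its genes, centred on the 20 libraries. For named genes with 1 to 3 counts in a group the ratio of summed counts is given with an exact 95% counting interval, and against 0 counts a lower bound from a floor of 3 counts over the group. Both cover counting error only. Correlations of fold changes that share Model libraries were set beside 50 simulations without effects and 20 splits of the Model libraries. Shared calls were set beside 5 simulations. Each gene was drawn independently in all these simulations. For 5 against 5 libraries, chance gives no overlap in 0.79% of genes.

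The alternatives fixed in advance were DESeq2 1.42.0, RLE size factors, no low-count filter, a fit of the 2 groups compared alone, sample quality weights (voomLmFit), the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out in turn. For correlations, genes above the median level were also used alone. A different pseudocount applies only to normalized values and was not run. Added after seeing the data were upper-quartile scaling and library size alone, the oviduct list mean and the mean of the granulosa and oocyte lists as 2 tissue covariates, leaving out the 2 libraries with no Zp3 count, and the mean of 3 genes nearly absent in Control as a covariate. Each comparison was also repeated on 100 splits of its 10 libraries, the real one included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.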

Results

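Messenger RNA was sequenced from 20 samples of mouse ovary in 4 labelled groups of 5 libraries: Control, Model, LNPIFN-Y and ptLNPIFN-Y. Per the series text, the study concerns lipid nanoparticles loaded with mRNA for interferon-γ (IFN-γ) in C57BL/6 mice that carry an orthotopic tumour of ID8Luci cells, where ID8 is a mouse line grown from ovarian surface epithelium. In that text the prefix pt stands for targeting by a peptide. The labels do not describe the particle without the prefix, and they do not say whether the 5 libraries of a group came from separate animals. The treatment arms of the series text that add anti-PD-1 antibody or cisplatin have no counterpart among these labels. No group is labelled as an empty particle or a particle with other mRNA. Effects of the IFN-γ mRNA and of the particle itself therefore cannot be told apart. Total counts per library ran from 16613167 to 16998557 in Control, from 16581478 to 17184097 in Model, from 16529892 to 17113937 in LNPIFN-Y and from 16496793 to 17218043 in ptLNPIFN-Y. Between 16441 and 17692 genes had a count in a library, and 15723 genes were tested. The labels do not divide the 20 libraries into batches, so a batch effect cannot be judged from them.

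Positions are those of the mouse build GRCm38.p6. Genes named in advance include Ifng (Entrez ID 15978, chromosome 10, 118441046 to 118445894), Irf1 (16362, chromosome 11, 53770014 to 53778374), Cxcl9 (17329, chromosome 5, 92321331 to 92328079), Cd274 (60533, chromosome 19, 29362107 to 29388095), Cd8a (12525, chromosome 6, 71373427 to 71379171), Mki67 (17345, chromosome 7, 135689784 to 135716450) and Msln (56047, chromosome 17, 25748613 to 25754378).

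The ovary samples differed in their content of oviduct, follicle and fat transcripts. The mean of 22 oviduct epithelium genes, on the log2 scale and centred on all libraries, was 1.81 ± 1.16 in Control, 0.71 ± 2.26 in Model, -1.35 ± 1.71 in LNPIFN-Y and -1.17 ± 1.96 in ptLNPIFN-Y (SD, n = 5). For 22 granulosa cell genes, the somatic cells of the follicle, the group means were 1.14 ± 0.3, 0.57 ± 0.81, -1.02 ± 1.93 and -0.69 ± 1.63 in the same order (SD, n = 5). Oocyte genes had group means of 1.11 ± 0.6, 0.39 ± 0.87, -0.77 ± 2.35 and -0.73 ± 1.98 (SD, n = 5). The libraries LNPIFN-Y 5 and ptLNPIFN-Y 5 had no count of the egg-coat gene Zp3, which is outside the naming rule. Adipocyte genes had group means of 0.43 ± 1.07, -0.44 ± 0.39, -0.53 ± 1.2 and 0.54 ± 1.42 (SD, n = 5). These differences run alongside the gene groups compared in the rest of the report.

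**Figure D1:**
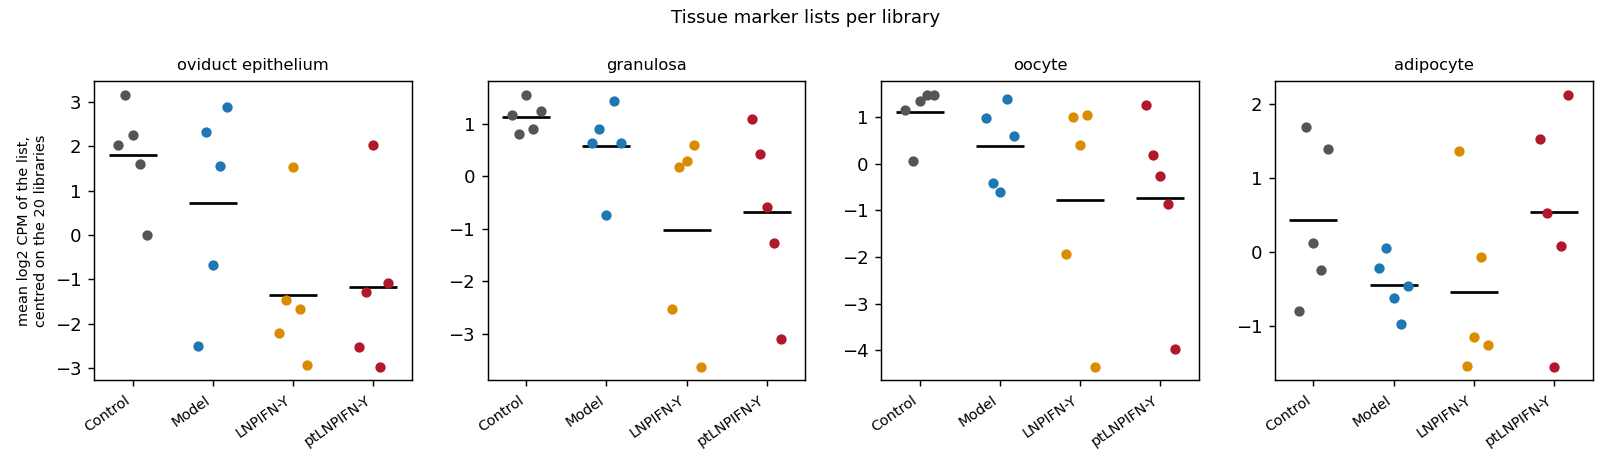
Mean log2 CPM of 4 tissue marker lists (vertical axis, centred on the 20 libraries) in each library, by group (horizontal axis); points are libraries and black lines are group means. Libraries of 1 group spread widely: the granulosa list ran from -3.63 to 0.6 in LNPIFN-Y against 0.81 to 1.56 in Control.

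The comparison of Model with Control asks how the ovary with the tumour model differs from the ovary without it. No single gene passed the test, and the gene lists that lay highest in Model were those of MHC class II, which presents peptides to CD4 T cells, of T cells, and of immediate-early genes. Their median log2 fold changes were 1.42, 0.86 and 0.74 (n = 5 per group). Without Model 3 the first 2 were 0.45 and 0.53, and without Model 2 the immediate-early median was 0.41. Cd8a and Cd8b1, the 2 chains of the CD8 co-receptor, averaged 2.31 ± 1.01 and 0.878 ± 0.334 CPM (edgeR counts scaled to library depth) in Model against 0.944 ± 0.269 and 0.289 ± 0.102 in Control (SD, n = 5). All 5 Model libraries lay above all 5 Control libraries for both genes, as happens by chance in 0.79% of genes and was seen in 125 genes (0.8%) in either direction, with log2 fold changes of 1.28 ± 0.36 and 1.57 ± 0.43 (SE) and an edgeR adjusted p of 0.841 each. Ifng itself had 4 counts over the 5 Control libraries and 10 over the 5 Model libraries.

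Of 13 MHC class II genes, 12 had a positive fold change and 0 passed the test over all genes, while 9 passed when p values were adjusted over the list alone. H2-Eb2, a class II chain, had a log2 fold change of 3.72 ± 1.04 (SE) and H2-DMb2, a chain of the class II peptide loader, 1.59 ± 0.49, both with an edgeR adjusted p of 0.841. Without Model 3, which held 206 counts of H2-Eb2 against 2 to 25 in the other 4, they were at 1.65 and 0.88. DESeq2 called H2-Eb2 (adjusted p 0.0278) with all libraries. The list mean of library Model 3 was 0.42, against a Model group mean of -1.27 ± 1 (SD, n = 5). The T cell list had 21 of 21 fold changes above 0, and 3 members passed when adjusted over the list alone. The list of IFN-γ response genes had 39 of 41 fold changes above 0, with a median of 0.5, and 5 passed when adjusted over the list alone. Gbp2b, an interferon-induced GTPase, was at 1.74 ± 1.15 CPM in Model and 0.295 ± 0.133 in Control (SD, n = 5), a log2 fold change of 2.54 ± 0.58 (SE, edgeR adjusted p 0.841, DESeq2 0.00404). Irf1, a transcription factor induced by IFN-γ, had a log2 fold change of 0.25 ± 0.21 (SE, edgeR adjusted p 0.936). The MHC class I list had 23 of 23 fold changes above 0 with a median of 0.29, and 1 passed when adjusted over the list alone. The type I interferon list had 26 of 32 above 0, and the NK and cytotoxic list 14 of 17, with 2 passing when adjusted over the list alone. Of 18 immediate-early genes 15 had positive fold changes and 7 passed when adjusted over the list alone, led by Fosb (3.46 ± 0.89) and Jun (0.97 ± 0.26), which encode parts of the AP-1 factor. Fosb was at 2.65 without Model 1, and it was called by DESeq2 (adjusted p 0.0117) but not by edgeR (0.841). Adipocyte genes had a median of -1.11 and oocyte genes of -0.63, with 2 of 16 and 1 of 31 fold changes above 0, the latter at -0.42 without Model 3 and -0.99 without Model 4. Without Model 3 the IFN-γ and MHC class I medians were 0.29 and 0.19. Mki67, a marker of cycling cells, and Msln, a mesothelial surface gene, had log2 fold changes of 0.04 ± 0.25 and 0.46 ± 0.51 (SE, edgeR adjusted p 0.978 and 0.936).

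With edgeR 0 genes were higher and 0 lower in Model at an adjusted p under 0.05. The unadjusted p was under 0.05 for 772 genes, where 786 are due by chance. Most of the 772 were higher in Model, a one-sided lean that the total does not show and whose cause was not tested. DESeq2 called 27 genes higher and 2 lower. The 2 genes DESeq2 called lower were the clock genes Per3 (DESeq2 log2 fold change -0.82, adjusted p 0.031) and Ciart (-1.15, 0.031), named after their values were seen. Their edgeR values were -0.82 ± 0.2 and -1.16 ± 0.29 (SE, adjusted p 0.841 each). With a preset correlation of 0.01 between genes, the camera set test called 15 lists higher and 5 lower, among them MHC class II (adjusted p 2.47e-08) and T cells (1.47e-13). With an estimated correlation it called 0 in either direction, and each of the lists named here gave an adjusted p = 0.349 or higher, as did fry at 0.359 or higher.

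The comparison of LNPIFN-Y with Model asks what the particle without the pt prefix changed in the ovary of the tumour model. Genes induced by interferon, genes of antigen presentation and genes of cytotoxic lymphocytes rose together. Irf1, which the series text names as a mediator of interest, rose from 53.4 ± 13.9 CPM in Model to 296 ± 92.1 in LNPIFN-Y (SD, n = 5), a log2 fold change of 2.47 ± 0.22 (SE, edgeR adjusted p 5.13e-07). The T cell chemokine Cxcl9 rose by 5.31 ± 0.73 (9.67e-05) and Cd274, the gene of the PD-1 ligand PD-L1, by 4.63 ± 0.35 (7.02e-08). Cd274 had been at 6.56 ± 2.29 CPM in Control and 7.06 ± 1.69 in Model and reached 174 ± 90.9 (SD, n = 5). Ifng rose by 3.28 ± 0.7 (edgeR adjusted p 0.00584), from 10 counts over the 5 Model libraries to 97 over the 5 LNPIFN-Y libraries, and the counts do not tell transcripts of the animal from delivered mRNA. Library LNPIFN-Y 2 held 52 of the 97 counts, and without it Ifng was at 2.56. Cxcl9 was at 6.32 without Model 3.

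Of 41 IFN-γ response genes 39 rose and 0 fell, with a median log2 fold change of 3.46. The same 39 were counted when p values were adjusted over the list alone. The remaining genes, Nos2 and Jak2, which are outside the naming rule, had values of 0.26 and 0.6. The members with the largest changes were the guanylate-binding GTPase Gbp10 (7.53 ± 0.5), the ubiquitin-like gene Ubd (6.91 ± 0.64) and the tryptophan-degrading enzyme Ido1 (6.12 ± 0.96, SE). Outside the list, Apol11b of the apolipoprotein L family rose by 6.04 ± 0.41 and Cngb3, an ion channel gene, went from 1 count over the Model libraries to 217, a ratio of 217 with a 95% counting interval of 38.5 to 8600. The smallest p values in the list belonged to the GTPase Tgtp1 (4.03 ± 0.21) and to Nlrc5, the transactivator of MHC class I (3.71 ± 0.22). Of 32 genes of the type I interferon response 31 rose (31 adjusted over the list alone), with a median of 2.45, among them Ifit3 (4.5 ± 0.35) and Stat2 (2.41 ± 0.15). Of 23 MHC class I genes 20 rose (22 adjusted over the list alone), with a median of 2.82. H2-Q4, a class I heavy chain of a gene family with similar copies, rose by 3.45 ± 0.18, from 55.8 ± 15.4 to 612 ± 50.3 CPM (SD, n = 5). Of 13 MHC class II genes 12 rose (12 adjusted over the list alone), with a median of 2.57, among them H2-DMa (3.13 ± 0.4) and H2-DMb2 (3.28 ± 0.5). Without Model 3, whose MHC class II list mean was the highest of its group, the list median was 3.6, H2-DMa was at 3.85, H2-DMb2 at 3.97 and Ubd at 7.54. Model 5 held 4 of the 5 Model counts of Ido1 and the only one of Cngb3. Without it the ratio of Ido1 was 282 (95% counting interval 50.3 to 11200) against 70.5 (29.9 to 219) with it, and Cngb3 was at least 57.8-fold higher (floor of 3 counts over the group). Without LNPIFN-Y 1 the ratio of Cngb3 was 114 (19.9 to 4540). Ubd was at 6.21 with tissue covariates.

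**Figure D2:**
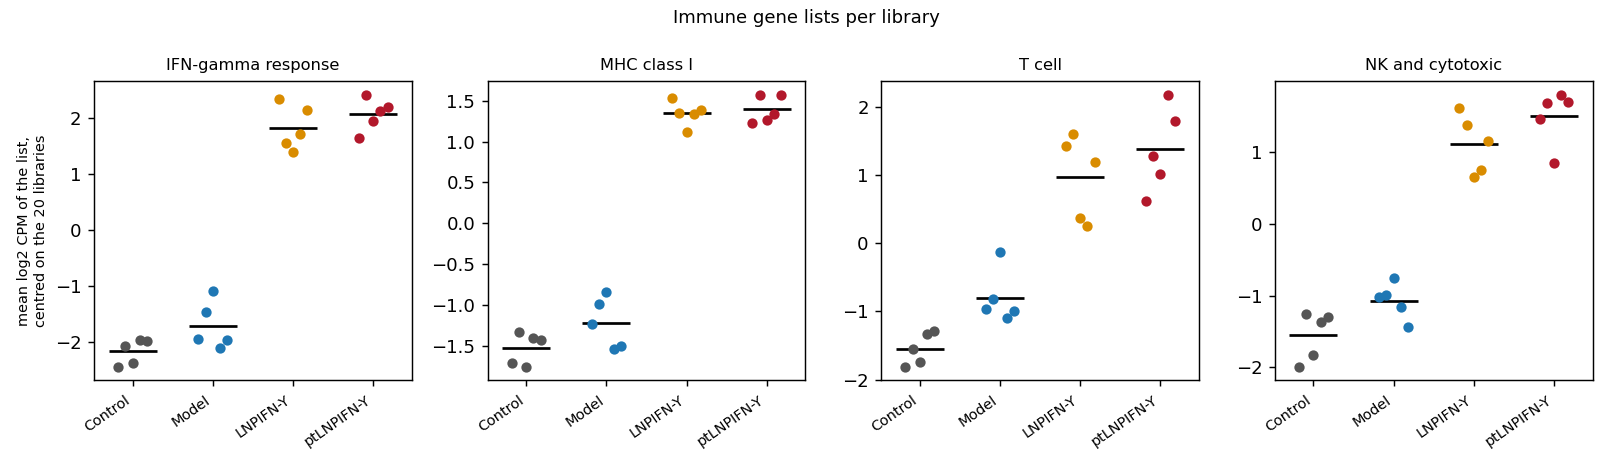
Mean log2 CPM of 4 immune gene lists (vertical axis, centred on the 20 libraries) in each library, by group (horizontal axis); points are libraries and black lines are group means. For the IFN-γ response list the Control and Model libraries lie between -2.45 and -1.09 and the particle libraries between 1.39 and 2.42.

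Lymphocyte genes rose as well in LNPIFN-Y. Of 21 T cell genes 18 rose (21 adjusted over the list alone), with a median of 2.07, among them Cd8a (1.99 ± 0.36, edgeR adjusted p 0.00151) and Cd3g of the T cell receptor complex (2.42 ± 0.36). Of 17 NK and cytotoxic genes 15 rose (17 adjusted over the list alone), with a median of 2.4. Gzmb, the protease granzyme B, rose by 4.57 ± 0.32 and the activating receptor gene Klrk1 by 3.72 ± 0.37 (SE). Of 21 checkpoint genes 9 rose (13 adjusted over the list alone), among them Cd274 and Lag3 (1.97 ± 0.27), whereas Pdcd1, the gene of PD-1, was not past the test at 0.43 ± 0.49 (edgeR adjusted p 0.668, a gene chosen after its values were seen). Of 33 genes of apoptosis and other cell death 16 rose and 0 fell (22 and 1 adjusted over the list alone), led by Zbp1, a sensor that starts necroptosis (4.77 ± 0.41), and Xaf1 (2.36 ± 0.27). Myeloid lists moved in part. Of 24 macrophage genes 9 rose (14 adjusted over the list alone). Of 15 dendritic cell genes 5 rose and Cd209a fell (10 and 1 adjusted over the list alone). Of 21 cytokine genes 9 rose (11 adjusted over the list alone), and of 16 complement genes 5 rose (9 adjusted over the list alone). With an estimated correlation the macrophage, cytokine and complement lists were not called. Examples chosen after their values were seen are the cross-presenting dendritic cell genes Xcr1 (3.69 ± 0.38) and Clec9a (2.56 ± 0.22), the chemokine Ccl5 (3.08 ± 0.46) and the complement gene C4b (2.59 ± 0.42).

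Mki67 and Msln were not past the test, at 0.13 ± 0.25 and 0.95 ± 0.52 (SE, edgeR adjusted p 0.822 and 0.338). None of the 35 tested genes of the G1/S list and none of the 41 of the G2/M list passed, with medians of 0.29 and 0.11. Of 19 p53 targets 1 fell, the stress gene Gadd45a (-0.88 ± 0.23, edgeR adjusted p 0.0223), a gene chosen after its value was seen. Its adjusted p was 0.0616 to 0.0818 when Model 2, Model 4, LNPIFN-Y 1, LNPIFN-Y 2 or LNPIFN-Y 4 was left out.

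The genes with the lowest fold changes under the naming rule were the kallikrein Klk1 (-2.46 ± 0.57, edgeR adjusted p 0.0115), the C-type lectin Cd209a (-2.08 ± 0.52, 0.0197), Fam171a2 (-1.69 ± 0.45, 0.0299), Psd (-1.26 ± 0.35, 0.0408) and the cytokine Il17d (-1.21 ± 0.33, 0.0353). The low calls were close to the threshold. Klk1 was at -1.8 (0.0484) without Model 2. Cd209a had an adjusted p of 0.0685 without Model 2 and 0.0611 without LNPIFN-Y 5. Fam171a2 had 0.0511 to 0.121 without Model 2, 4 or 5 or LNPIFN-Y 1, 2, 4 or 5. Psd had 0.0823 to 0.147 without Model 2 or 4 or LNPIFN-Y 1, 2 or 4, and Il17d had 0.0547 to 0.0907 without Model 2 or 4 or LNPIFN-Y 1, 2 or 5. With the oviduct and follicle list means as covariates, an alternative chosen after seeing the data, none of the 5 passed. Klk1 was at -1.51 (adjusted p 0.0996), Fam171a2 at -0.94 (0.142) and Psd at -0.9 (0.359), while Cd209a at -2.2 (0.053) and Il17d at -1.09 (0.0734) had folds about as large as before. With the replicate number as a block, Cd209a, Fam171a2, Psd and Il17d had an adjusted p of 0.0538 to 0.0771, and without the 2 libraries with no Zp3 count 0.0538 to 0.0875. Psd was at 0.0512 with no low-count filter. The oviduct, granulosa, oocyte, smooth muscle and cholesterol synthesis lists had medians of -1.91, -0.81, -0.41, -0.82 and -0.39, and camera with the preset correlation called all 5 lower. With an estimated correlation their adjusted p = 0.603, 0.603, 0.779, 0.603 and 0.728. The oviduct median was -1.27 without Model 5 and -3.64 without LNPIFN-Y 3, and the granulosa median was -0.53 without LNPIFN-Y 5. The oocyte median was -0.66 without Model 3, -0.06 without Model 4, -0.11 without LNPIFN-Y 1, -0.76 without LNPIFN-Y 2 and -0.78 without LNPIFN-Y 4, and its call was lost without LNPIFN-Y 5 (-0.09, adjusted p 0.397). The smooth muscle call was lost without Model 1 (0.0501) and its median was -0.51 without Model 2. The cholesterol synthesis call was lost without Model 1 (0.0855), Model 5 (-0.14, 0.374) or LNPIFN-Y 5 (0.085). Among the members of these lists only Grem1 was called, a gene chosen after its value was seen. It had 449 counts over the Model libraries and 3 over the LNPIFN-Y libraries, a ratio of 150 with a 95% counting interval of 50.9 to 729 (fitted log2 fold change -6.82 ± 1.82, edgeR adjusted p 0.0299). The call was lost at 0.0514 to 0.0838 without Model 2 or 4 or any 1 of LNPIFN-Y 1, 2, 3, 4 or 5. The ratio was 97.5 (32.9 to 476) without Model 4 and 359 (64 to 14200) without LNPIFN-Y 5. With tissue covariates the fitted value was -4.88 (0.444), and with the replicate number as a block the adjusted p was 0.126.

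In all, 825 genes were higher and 89 lower in LNPIFN-Y at an edgeR adjusted p under 0.05, with median log2 fold changes of 1.83 and -0.55, and 820 genes had no overlap between the groups (5.22%, against 0.79% by chance). With library size alone in place of TMM factors the split was 751 higher and 219 lower, and that scaling shifted the median of all genes to -0.132. The count of higher genes was 1246 without Model 3. The count of lower genes was 29 without Model 2, 32 without Model 4, 37 without LNPIFN-Y 1, 39 without LNPIFN-Y 5, 52 without Model 5, 214 without Model 1, 249 without LNPIFN-Y 3 and 486 without Model 3. DESeq2 gave 1028 and 492, sample quality weights 1339 and 580, the 2 groups compared alone 543 and 8, and the fit with tissue covariates 538 and 18. The count of lower genes was 33 with the replicate number as a block, and 37 without the 2 libraries with no Zp3 count. With the preset correlation 14 lists were higher and 5 lower, the latter 3 without Model 1 and 3 without LNPIFN-Y 5, and with an estimated correlation 9 and 0. The 9 were the IFN-γ (adjusted p = 0.0019), type I interferon (0.00493), MHC class I (0.000926), MHC class II (0.0309), checkpoint (0.0169), T cell (0.0448), NK and cytotoxic (0.00498), dendritic cell (0.0448) and cell death lists (0.0448). The macrophage, cytokine, complement, B cell and G1/S calls were lost, at an adjusted p = 0.238, 0.135, 0.103, 0.603 and 0.603 with an estimated correlation.

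**Figure D3:**
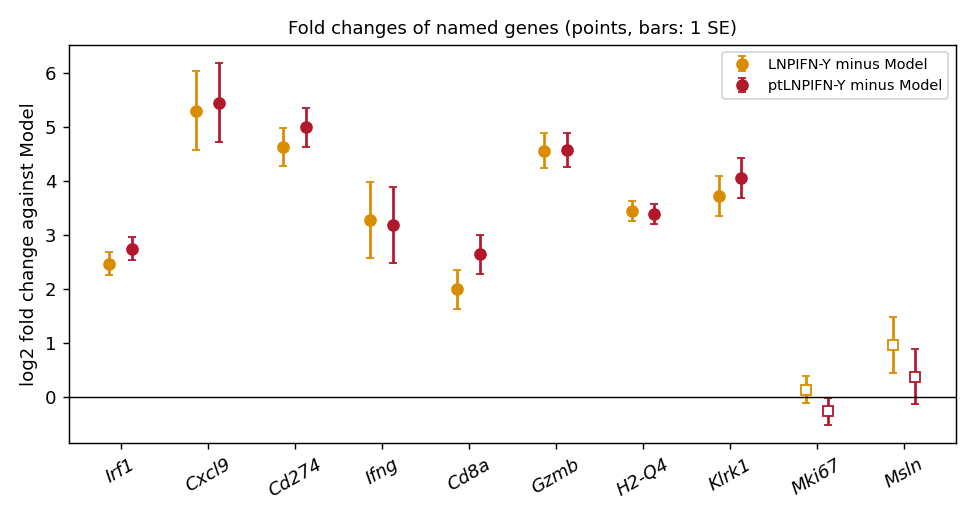
Log2 fold changes against Model (vertical axis) of named genes (horizontal axis) in LNPIFN-Y and ptLNPIFN-Y; points are estimates of the edgeR fit with bars of 1 standard error (n = 5 per group), filled where the adjusted p is under 0.05 and open where it is not. Cd274 stands at 4.63 and 5, while Mki67 stands at 0.13 and -0.27.

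The comparison of ptLNPIFN-Y with Model asks the same of the particle with the pt prefix. The interferon, antigen presentation and lymphocyte genes rose here too. Irf1 rose by 2.75 ± 0.22 on the log2 scale (SE, edgeR adjusted p 1.44e-07), to 360 ± 77.9 CPM (SD, n = 5), Cxcl9 by 5.46 ± 0.74 (6.67e-05) and Cd274 by 5 ± 0.36 (2.9e-08). Cd8a rose by 2.64 ± 0.37 (9.68e-05), from 2.31 ± 1.01 to 14.4 ± 5.34 CPM (SD, n = 5). Ifng rose by 3.19 ± 0.7 (0.00613), with 89 counts over the 5 libraries against 10 in Model. Without Model 3 Cxcl9 was at 6.48.

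Of 41 IFN-γ response genes 39 rose (39 adjusted over the list alone), with a median of 3.69. The largest changes were those of Ubd (8.12 ± 0.66), Gbp10 (8.03 ± 0.51), Ido1 (6.93 ± 0.98) and Gbp2b (6.36 ± 0.52), and Cngb3 went from 1 count to 454, a ratio of 457 after scaling for depth with a 95% counting interval of 81.6 to 18100. Of 32 type I interferon genes 31 rose (31 adjusted over the list alone), with a median of 2.53, and of 23 MHC class I genes 20 rose (20 adjusted over the list alone), with a median of 2.8. Of 13 MHC class II genes 12 rose (12 adjusted over the list alone), with a median of 2.72. Tgtp1 (4.49 ± 0.21), Nlrc5 (3.9 ± 0.22), Ifit3 (4.83 ± 0.36), Stat2 (2.36 ± 0.15), H2-Q4 (3.39 ± 0.18), H2-DMa (3.23 ± 0.4) and H2-DMb2 (3.83 ± 0.51) are the examples the rule picked. Without Model 3 the MHC class II median was 3.7, H2-DMa was at 3.96, H2-DMb2 at 4.53 and Ubd at 8.78. Without Model 5 the ratio of Ido1 was 501 (95% counting interval 89.6 to 19800) against 125 (53.4 to 387) with it, and Cngb3 was at least 122-fold higher (floor of 3 counts over the group). Ubd was at 7.4 with tissue covariates. All 17 NK and cytotoxic genes rose (17 adjusted over the list alone), with a median of 2.78, among them Gzmb (4.58 ± 0.32) and Klrk1 (4.06 ± 0.38). Of 21 T cell genes 19 rose (21 adjusted over the list alone), with a median of 2.48, among them Cd3g (2.86 ± 0.37) and the kinase Lck (2.1 ± 0.27). Of 21 checkpoint genes 13 rose (13 up and 1 down adjusted over the list alone), among them Lag3 (2.13 ± 0.27), and Pdcd1 was again not past the test at 0.66 ± 0.49 (edgeR adjusted p 0.418). Of 33 cell death genes 16 rose (21 adjusted over the list alone), led by Zbp1 (4.86 ± 0.42) and Xaf1 (2.48 ± 0.28). Of 15 B and plasma cell genes 6 rose (11 up and 1 down adjusted over the list alone), a list in which 0 of 15 passed over all genes for LNPIFN-Y. Camera with the preset correlation called the list higher than in Model for both particles. Its list means were 2.398 and 1.849 in ptLNPIFN-Y 4 and 5, against -0.295 to 0.658 in the other libraries of that group. They were 0.248 to 0.939 in LNPIFN-Y and -0.965 to 0.131 in Model. The difference between the 2 particles in this list had a median of 0.99, with 0 genes past the test. The list call for the difference between the 2 particles was lost without LNPIFN-Y 1 (0.149), LNPIFN-Y 4 (0.0704), ptLNPIFN-Y 4 (median 0.52, 0.98) or ptLNPIFN-Y 5 (0.424), and with an estimated correlation, at an adjusted p = 0.635. Of 15 dendritic cell genes 9 rose and Cd209a fell (10 and 1 adjusted over the list alone). In the macrophage, cytokine and complement lists 7 of 24, 9 of 21 and 7 of 16 genes rose (12, 12 and 8 adjusted over the list alone). With an estimated correlation those 3 lists were not called.

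Mki67 and Msln were not past the test, at -0.27 ± 0.25 and 0.37 ± 0.51 (SE, edgeR adjusted p 0.507 and 0.677). Of 41 G2/M genes 5 had a positive fold change and 0 passed, with a median of -0.24, which camera with the preset correlation called lower (adjusted p 0.0125), at an adjusted p = 0.807 with an estimated correlation. With the preset correlation that call was lost without Model 1 (0.161), Model 3 (0.221) or ptLNPIFN-Y 5 (median -0.14, 0.223). Of 19 p53 targets 1 fell, again Gadd45a, which is outside the naming rule (-0.82 ± 0.23, edgeR adjusted p 0.0318). Its adjusted p was 0.0524 to 0.103 when Model 2, 4 or 5 or ptLNPIFN-Y 1, 2, 4 or 5 was left out. The lowest genes under the naming rule were Fcrls, an Fc receptor-like gene of resident macrophages (-3.05 ± 0.73, edgeR adjusted p 0.013), Cd209a (-2.3 ± 0.53, 0.0091), the cadherin Fat3 (-2.17 ± 0.44, 0.00326), the cardiac troponin Tnnt2 (-2.03 ± 0.59, 0.0438) and the receptor gene Cntfr (-1.69 ± 0.48, 0.0376). Tnnt2 had an adjusted p of 0.0507 to 0.11 without Model 1, 2, 4 or 5 or ptLNPIFN-Y 1, 2 or 5, and Cntfr had 0.0529 to 0.106 without Model 2, 4 or 5 or ptLNPIFN-Y 2, 4 or 5. With tissue covariates Tnnt2 was at -1.36 (0.15), Cntfr at -0.87 (0.083), Fat3 at -1.45 (0.0126) and Fcrls at -4.08 (8.38e-05). Tnnt2 and Cntfr had 0.0726 and 0.0707 with the replicate number as a block, and Tnnt2 had 0.0536 with no low-count filter and 0.0812 without the 2 libraries with no Zp3 count. The 14 smooth muscle genes had a median of -1.18, and 8 fell when adjusted over the list alone while 0 did over all genes. Library ptLNPIFN-Y 4 had a smooth muscle list mean of -2.77, against -0.86 to 0.17 in the other 4. The oviduct, granulosa and oocyte lists had medians of -1.7, -0.76 and -0.66, the oxidative phosphorylation list 0.15 and the adipocyte list 1.68. In the adipocyte list 7 rose when adjusted over the list alone and 0 over all genes. For the smooth muscle, oviduct, granulosa, oocyte, oxidative phosphorylation and adipocyte lists the adjusted p = 0.332, 0.689, 0.689, 0.787, 0.701 and 0.689 with an estimated correlation. With the preset correlation all 6 were called, with exceptions when 1 library was left out. The oviduct median was -0.92 without Model 5 and -2.94 without ptLNPIFN-Y 3. Without ptLNPIFN-Y 1 the granulosa and oocyte medians were -1.55 and -1.44. The granulosa call was lost without ptLNPIFN-Y 5 (0.133), and the oocyte call without Model 1 (0.0634), Model 4 (-0.32, 0.063) or ptLNPIFN-Y 5 (-0.35, 0.317). The oxidative phosphorylation call was lost without Model 3 (0.0738), ptLNPIFN-Y 1 (0.0516) or ptLNPIFN-Y 5 (0.04, 0.309), and its median was 0.24 without ptLNPIFN-Y 3. The adipocyte call was lost without Model 3 (0.0528), ptLNPIFN-Y 1 (0.0889) or ptLNPIFN-Y 5 (1.16, 0.133).

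In all, 951 genes were higher and 149 lower in ptLNPIFN-Y at an edgeR adjusted p under 0.05, with median log2 fold changes of 1.91 and -0.62, and 954 genes had no overlap between the groups (6.07%, against 0.79% by chance). With library size alone the split was 900 higher and 731 lower, and that scaling shifted the median of all genes to -0.171. The count of higher genes was 1578 without Model 3. The count of lower genes was 57 without ptLNPIFN-Y 5, 70 without Model 4, 74 without ptLNPIFN-Y 4, 80 without Model 2, 245 without ptLNPIFN-Y 3, 290 without ptLNPIFN-Y 1 and 685 without Model 3. DESeq2 gave 1278 and 627, sample quality weights 1946 and 766, the 2 groups compared alone 670 and 44, and the fit with tissue covariates 716 and 101. The count of lower genes was 79 with the replicate number as a block, 97 without the 2 libraries with no Zp3 count, 226 with upper-quartile scaling and 86 with the covariate of genes nearly absent in Control. With the preset correlation 15 lists were higher and 5 lower, the latter 3 without Model 1 and 3 without ptLNPIFN-Y 5, and with an estimated correlation 9 and 0, which were the IFN-γ (adjusted p = 0.00319), type I interferon (0.00627), MHC class I (0.00246), MHC class II (0.0335), checkpoint (0.0145), T cell (0.0335), NK and cytotoxic (0.00479), dendritic cell (0.0335) and cell death lists (0.0335). The macrophage, cytokine, complement and B cell calls were lost, at an adjusted p = 0.332, 0.131, 0.131 and 0.332 with an estimated correlation.

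The direct comparison of ptLNPIFN-Y with LNPIFN-Y asks whether the 2 particles differed. No gene passed the test in either direction. Irf1 differed by 0.28 ± 0.21, Cxcl9 by 0.15 ± 0.61, Cd274 by 0.37 ± 0.3 and Ifng by -0.08 ± 0.59 on the log2 scale (SE, n = 5 per group, edgeR adjusted p 1 each). The 95% interval for Irf1 ran from -0.16 to 0.73 and that for Ifng from -1.34 to 1.17, so differences within those ranges are not ruled out by these libraries. Cd8a differed by 0.65 ± 0.35, Mki67 by -0.4 ± 0.25 and Msln by -0.58 ± 0.51 (edgeR adjusted p 1 each).

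Some lists lay to one side across nearly all members, several of them carried by 1 or 2 libraries. With an estimated correlation none of the lists named in this part was called (adjusted p = 0.555 each), and the calls below are those with the preset correlation. None of 41 G2/M genes had a positive fold change, with a median of -0.33, and Kif2c, a mitotic kinesin, was at -0.48 ± 0.22 (SE) and Ect2, a cytokinesis gene, at -0.6 ± 0.29. Without LNPIFN-Y 5 the G2/M median was -0.14 and Ect2 was at -0.16. Without both LNPIFN-Y 5 and ptLNPIFN-Y 5, the 2 libraries with no Zp3 count, the median was -0.04 and the list was not called (adjusted p 0.997), nor was it with all libraries and an estimated correlation (adjusted p = 0.555). Fibroblast and matrix genes had a median of -0.45, among them the protease Mmp14 (-0.65 ± 0.26) and the collagen cross-linker Loxl2 (-0.87 ± 0.35). Without LNPIFN-Y 5 the median was -0.22, Mmp14 was at -0.22 and Loxl2 at -0.47. All 16 adipocyte genes were positive, with a median of 1.12, among them Gpd1 (1.72 ± 0.67) and Retn (1.66 ± 0.82), and 21 of 22 cholesterol synthesis genes were positive, with a median of 0.58, among them Pmvk (1.11 ± 0.36) and Nsdhl (1.04 ± 0.34). The adipocyte median was 2 without LNPIFN-Y 1, 0.63 without ptLNPIFN-Y 5 and 0.38 without both LNPIFN-Y 5 and ptLNPIFN-Y 5, and the cholesterol synthesis median was 0.28 without ptLNPIFN-Y 2. All 30 oxidative phosphorylation genes were positive, with a median of 0.15, among them Ndufs3 (0.27 ± 0.11) and Ndufb3 (0.31 ± 0.15), but the median was 0.24 without ptLNPIFN-Y 3, and without ptLNPIFN-Y 5 it was 0.04 and the call was lost (adjusted p 0.147), as it was with an estimated correlation (adjusted p = 0.555). The T cell list had 20 of 21 positive values (median 0.39), the NK and cytotoxic list 17 of 17 (0.38), the IFN-γ list 36 of 41 (0.22), and the G1/S list 4 of 35 (-0.19). The T cell median was 0.24 without LNPIFN-Y 4 and 0.16 without ptLNPIFN-Y 4, and the NK and cytotoxic median 0.24 without LNPIFN-Y 3. The IFN-γ median was 0.41 without LNPIFN-Y 1 and 0.13 without ptLNPIFN-Y 2. The G1/S median was -0.07 without LNPIFN-Y 5, and its call was lost without both LNPIFN-Y 5 and ptLNPIFN-Y 5 (-0.04, adjusted p 0.679) and with an estimated correlation (adjusted p = 0.555). Members the rule picked there were Cd8b1 (0.71 ± 0.39), Eomes (0.93 ± 0.35), Klre1 (0.47 ± 0.29), Tyms (-0.31 ± 0.13) and Clspn (-0.5 ± 0.25).

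With edgeR 0 genes were higher and 0 lower, 481 had an unadjusted p under 0.05 where 786 are due by chance, and DESeq2 also called 0 and 0. Camera with the preset correlation called 11 lists higher and 6 lower, which became 7 higher without ptLNPIFN-Y 4, and with an estimated correlation it called 0 and 0, where the G2/M list and each of the other lists of this comparison named here had an adjusted p = 0.555. On counts simulated for this comparison, the test found 51% of genes with a 2-fold change and 67% of genes with a 4-fold change. The simulation left low-count genes unchanged and drew each gene independently. These shares therefore do not cover low-count genes or variation shared across genes, such as tissue content.

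In the main fit, the comparisons of both particle groups with Control had the largest counts of changed genes. That order did not hold with tissue covariates, where LNPIFN-Y had fewer calls against Control than ptLNPIFN-Y against Model. In LNPIFN-Y 1699 genes were higher and 515 lower than in Control, and in ptLNPIFN-Y 1916 were higher and 847 lower (edgeR, n = 5 per group). The IFN-γ list rose in 39 of 41 members in both, with medians of 4.15 and 4.36, and the T cell list in 20 and in 21 of 21 members, with medians of 3.11 and 3.67. The NK and cytotoxic list rose in 17 of 17 members in both, the MHC class II list in 12 of 13, and the B and plasma cell list in 6 and 12 of 15. Adjusted over the list alone, 40 and 40 IFN-γ genes, 21 and 21 T cell genes, 17 and 17 NK and cytotoxic genes, 12 and 12 MHC class II genes and 11 and 12 B and plasma cell genes rose. For LNPIFN-Y the MHC class II and T cell calls were lost at an adjusted p = 0.0547 each with an estimated correlation, and the B and plasma cell calls at 0.391 and 0.274. The oviduct and granulosa lists had medians of -2.33 and -1.37 in LNPIFN-Y and of -1.84 and -1.31 in ptLNPIFN-Y, with adjusted p = 0.545, 0.576, 0.574 and 0.626 with an estimated correlation. With upper-quartile scaling the splits were 1490 higher and 1029 lower for LNPIFN-Y and 1682 and 1423 for ptLNPIFN-Y, and with library size alone 1372 and 1265, and 1491 and 2241. These scalings shifted the median of all genes to -0.126 and -0.122 and to -0.162 and -0.191. For LNPIFN-Y the count of higher genes was 1120 without Control 3, and that of lower genes was 189 without Control 2, 192 without LNPIFN-Y 1, 201 without LNPIFN-Y 5, 245 without Control 3, 340 without Control 1 and 1411 without LNPIFN-Y 3. For ptLNPIFN-Y the count of lower genes was 303 without ptLNPIFN-Y 5, 357 without ptLNPIFN-Y 4, 453 without Control 3, 455 without Control 2, 499 without Control 1, 500 without ptLNPIFN-Y 2 and 1417 without ptLNPIFN-Y 1.

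The response to the particles did not run against the change in the model. Across genes, which are not independent replicates, the fold changes of LNPIFN-Y against Model correlated with those of Model against Control at r = 0.574, and those of ptLNPIFN-Y at r = 0.517. With no effects the shared Model libraries give -0.5 and -0.502 in simulations that draw each gene independently. Such simulations hold no variation shared by many genes of a library, such as tissue content. The oviduct and granulosa list means fell from Control to Model and further in both particle groups, so tissue content may also give a positive r. That was not tested. The covariances were 0.211 and 0.199 against a simulated -0.109, a difference of 0.32 and 0.307. With the Model libraries split between the comparisons, the mean r was 0.566 and 0.529 over 20 splits, but single splits ran from -0.048 to 0.837 and from -0.067 to 0.786. Without Model 1 the values were 0.341 and 0.34, without Model 3 they were 0.374 and 0.347, and among genes above the median level they were 0.448 and 0.303.

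The responses to the 2 particles resembled each other across all genes and in the higher calls. For the lower calls, the split of the Model libraries does not decide the question. Their correlation across genes was 0.925, against 0.5 from shared Model libraries alone in the same simulations of independent genes. It was 0.681 with the Model libraries split (0.335 to 0.805 over 20 splits). The covariance was 0.652 against a simulated 0.109. Of the genes called higher, 757 were shared by both comparisons, where independent lists share 49.9 and simulated groups with no effect share 0. Groups simulated without effects hold no true changes to call, so that 0 is no yardstick for the 757. Those simulated groups also leave out variation shared across genes. With the Model libraries split, 366.4 were shared on average of 568 and 662.6 called. Of the genes called lower, 32 were shared, where independent lists share 0.843, and with the Model libraries split 1.05 were shared of 114.4 and 121.2 called, where independent lists share 0.244. With the split, each comparison kept only a part of the Model libraries, and the values are means over 20 splits. The few shared lower genes therefore do not show that the 2 particles differed there.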

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

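The tests of scaling, tissue share, nearly absent genes and clock genes, and the splits of Model against Control, were chosen after the result was seen; the other splits were planned.

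In 396 groups of 5 libraries, 23 had 1 library far from the rest, by the gap to its nearest neighbour over the range of the group. Chance gives about 1 in 20, which is 19.8 here. In list means, on the centred log2 scale, these were T cells in Model 3 (ratio 0.714; -0.13 against -1.1 to -0.82), G2/M in ptLNPIFN-Y 5 (0.819, low), theca in Control 2 (0.819, low), luteal genes in Control 2 (0.903, low), oocyte genes in Control 2 (0.767, low), EMT genes in Model 5 (0.728, low), and erythroid genes in LNPIFN-Y 5 (0.766, low) and ptLNPIFN-Y 5 (0.77, high). Among genes they were Cd8a in Control 1 (0.767, low), Tgtp2 in Model 3 (0.759, high), Jun in Model 5 (0.736, low), Cngb3 in Model 5 (1, its single count), Il17d in LNPIFN-Y 5 (0.713, low), H2-Q4 in ptLNPIFN-Y 2 (0.938, high), H2-DMa in Model 3 (0.733, high), Lag3 in LNPIFN-Y 1 (0.811, high), Tnnt2 in ptLNPIFN-Y 4 (0.796, low), Ect2 in LNPIFN-Y 5 (0.728, high) and ptLNPIFN-Y 5 (0.74, low), Loxl2 in Control 2 (0.746, low) and LNPIFN-Y 5 (0.72, high), Clspn in ptLNPIFN-Y 5 (0.722, low) and Klre1 in Model 5 (0.782, low).

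Other splits of the same 10 libraries into 5 and 5 were called in the same way. For LNPIFN-Y against Model, 3 of 100 splits gave as many calls as the real one, which had 914, and the highest other had 1779. For ptLNPIFN-Y against Model it was 2 of 100, with 1100 calls and 3569 in the highest other. Against Control it was 1 of 100 for LNPIFN-Y (2214, highest other 1070) and 1 of 100 for ptLNPIFN-Y (2763, highest other 366). Splits matched these 4 counts at a share under 0.05, so chance alone seldom gives such counts, but it is not excluded. The labels do not say whether libraries came from separate animals, so the splits do not speak to differences between animals. For Model against Control and for ptLNPIFN-Y against LNPIFN-Y, 100 of 100 splits gave as many as the real 0, with 11 and 1764 in the highest other, but every split has at least 0 calls, so these 2 counts say nothing about chance. Splits that call more genes than the real one point to a structure of the samples. The highest splits against Model put Model 1, 2, 4 and 5 with LNPIFN-Y 4 or with ptLNPIFN-Y 1, so Model 3 sat with the particle libraries, yet its IFN-γ list mean of -1.09 lay below the particle libraries' lowest of 1.39. The split with 1764 calls put LNPIFN-Y 1 and 5 with ptLNPIFN-Y 3, 4 and 5.

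The first pattern is a set of 3 genes, Foxd1, Mybphl and Pax3, with at most 5 counts over the Control libraries and counts in every Model library. Mybphl and Pax3 had 0 counts in Control, so Model was at least 229-fold and at least 189-fold higher (floor of 3 counts over the group), but Model 3 held 566 of 690 and 505 of 569 of their Model counts, and without it the bounds were 51.3-fold and 26.5-fold; DESeq2 called Mybphl (adjusted p 1.51e-07), Pax3 (7.09e-07) and Foxd1 (0.0094) higher in Model than in Control and edgeR did not (0.841 each). Their mean was higher in LNPIFN-Y than in Model by 2.16 (exact p 0.119) and in ptLNPIFN-Y by 2.34 (0.111), so neither difference passed. Across the 10 particle libraries the mean rose with the IFN-γ list (r = 0.657, permutation p 0.0407, Spearman 0.564 with p 0.096) and with the mesothelial list (r = 0.715, p 0.0209, Spearman 0.624 with p 0.0599), and with tissue covariates the difference went from 2.25 ± 0.94 to 1.56 ± 0.95 (SE, 15 libraries). An interferon response, a larger share of tumour or surface cells, and loss of ovarian tissue may each contribute, and none is excluded.

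The second pattern is the genes lower in the particle groups than in Model. Of 89 lower calls in LNPIFN-Y at least 87 were called again with RLE, upper-quartile or library-size scaling, and of 149 in ptLNPIFN-Y at least 148, but these scalings all shift the median gene lower than TMM does (to -0.048 to -0.132 against -0.03, and to -0.053 to -0.171 against -0.042), so the recount decides nothing and scaling stays open. With tissue covariates the median of the 149 went from -0.62 to -0.52, 0.848 of its size. The median of the 89 went from -0.55 to -0.42, 0.75 of its size. The cutoffs for a verdict were set after the results were seen. The covariates cover oviduct and follicle tissue only, and not smooth muscle for example, so these medians do not decide on tissue share. Of the 89 and 149 genes, 9 and 52 were still called with these covariates, and all 89 and all 149 kept their sign. Higher calls were lost too, with 529 of 825 and 697 of 951 called again. Lost calls can follow from the added covariates themselves, so they do not decide on tissue share, which stays open.

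The third pattern is in clock genes, which were picked after Per3 and Ciart were seen. The mean of 9 evening-type genes, Per3 and Ciart among them, was lower in Model than in Control by -0.57 on the log2 scale. That of 5 morning-type genes was higher by 0.3, a difference of -0.87 (exact p 0.00794 over 252 splits, in part owed to the choice of these 2 genes). Single genes did not all follow: Cry1, of the morning type, was at -0.39 and Nr1d1, of the evening type, at 0.02. The morning-type genes alone had an exact p of 0.0397, adjusted over 5 tests 0.0662. Without Per3 and Ciart the difference was -0.76 ± 0.21 (SE, exact p 0.0159, adjusted over 5 tests 0.0398) and with tissue covariates -0.81 ± 0.22, which argues against the share of oviduct and follicle tissue as the whole cause. Against Control the score of all 14 genes was also lower in LNPIFN-Y (-0.45, exact p 0.0556) and ptLNPIFN-Y (-0.5, 0.0317), and without Per3 and Ciart by -0.35 (0.103) and -0.36 (0.0952). Collection at different times of day may explain it, the labels give no times, and an effect of the tumour model on the clock was not tested and stays open.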

How the results depend on the processing

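Upper-quartile and library-size scaling, tissue covariates, the covariate of 3 genes nearly absent in Control and the omission of LNPIFN-Y 5 and ptLNPIFN-Y 5 (no Zp3 count) were tests chosen after the result was seen; the others were planned. Except where fewer libraries, a fold threshold or a larger correlation between genes explain a smaller count by construction, the cause was not tested.

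For named genes, 2771 of 2975 values kept their direction and side of the threshold, 165 lost a call, 16 gained one and 23 reversed. Single genes were not tallied with RLE size factors, the 2 groups compared alone, sample quality weights or the covariate of genes nearly absent in Control. The 25 genes of the rule higher in each particle group than in Model stayed past the test in every alternative tallied. Many of them were picked for no overlap or for the smallest p, which favours such stability. Genes named after their values were seen did not all stay, such as Mup22 in ptLNPIFN-Y, which lost its call with tissue covariates (4.02).

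With DESeq2, 27 genes were higher and 2 lower in Model than in Control, against 0 and 0 with edgeR (edgeR unadjusted p under 0.05: 665 higher and 107 lower). DESeq2 gave 492 lower genes for LNPIFN-Y against Model (89 with edgeR), 627 for ptLNPIFN-Y against Model (149), 1428 for LNPIFN-Y against Control (515) and 1712 for ptLNPIFN-Y against Control (847). With only the 2 groups compared in the fit, LNPIFN-Y against Model gave 543 higher and 8 lower genes (825 and 89), ptLNPIFN-Y against Model 44 lower, and the comparisons with Control 799 and 1299 lower. With sample quality weights the counts against Model were 1339 and 580 for LNPIFN-Y and 1946 and 766 for ptLNPIFN-Y, and against Control 2735 and 2427, and 3443 and 2646 (1699 and 515, and 1916 and 847 in the main edgeR fit). The weights came with a different test, voomLmFit, so these changes cannot be credited to the weights alone. With an absolute log2 fold change of at least 1 the lower genes were 34 and 49 against Model, and against Control 1121 higher and 200 lower, and 1189 and 301.

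With upper-quartile scaling ptLNPIFN-Y against Model had 226 lower genes, and the comparisons with Control 1029 and 1423. With library size alone these were 731, 1265 and 2241, and LNPIFN-Y against Model had 219. With tissue covariates LNPIFN-Y against Model had 538 higher and 18 lower genes, LNPIFN-Y against Control 560 and 20 and ptLNPIFN-Y against Control 746 and 80. Without LNPIFN-Y 5 and ptLNPIFN-Y 5 the lower genes were 37 and 97 against Model and 147 and 488 against Control. With the covariate of genes nearly absent in Control, ptLNPIFN-Y against Model had 86 lower genes.

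With the replicate number as a block the lower genes were 33 for LNPIFN-Y and 79 for ptLNPIFN-Y against Model and 303 for LNPIFN-Y against Control, and Ifng in ptLNPIFN-Y against LNPIFN-Y went from -0.08 to 0.23. The numbers are not stated to pair samples. In a check of the pairing, 30 correlations between libraries of the same number ran from -0.698 to 0.76, and the own number was highest in 5.

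With 1 library left out, LNPIFN-Y against Model had 595 (without Model 4) to 1246 (without Model 3) higher and 29 (without Model 2) to 486 (without Model 3) lower genes. For ptLNPIFN-Y against Model it was 713 (without Model 4) to 1578 (without Model 3) higher and 57 (without ptLNPIFN-Y 5) to 685 (without Model 3) lower. LNPIFN-Y against Control had 1120 (without Control 3) to 1865 (without LNPIFN-Y 3) higher and 189 (without Control 2) to 1411 (without LNPIFN-Y 3) lower, and ptLNPIFN-Y against Control 303 (without ptLNPIFN-Y 5) to 1417 (without ptLNPIFN-Y 1) lower.

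With an estimated correlation, and also with tissue covariates and an estimated correlation, 0 lists were higher and 0 lower in Model than in Control (15 and 5 with the preset correlation) and in ptLNPIFN-Y than in LNPIFN-Y (11 and 6), and 9 were higher and 0 lower in each particle group than in Model (14 and 5, 15 and 5). Fry gave 0 and 0 in the first 2 comparisons, 0 lower in LNPIFN-Y and 1 lower in ptLNPIFN-Y than in Model. With tissue covariates and the preset correlation 2 lists were lower in Model than in Control and 0 in LNPIFN-Y than in Model. Without the libraries with no Zp3 count 3 lists were lower in each particle group than in Model, and with sample quality weights 17 were higher in ptLNPIFN-Y than in LNPIFN-Y. With 1 library left out, lists lower than in Model numbered 3 (without Model 1 or LNPIFN-Y 5) to 5 for LNPIFN-Y and 3 (without Model 1 or ptLNPIFN-Y 5) to 6 for ptLNPIFN-Y, and lists higher in ptLNPIFN-Y than in LNPIFN-Y 7 (without ptLNPIFN-Y 4) to 16 (without LNPIFN-Y 5).

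The values that reversed were all of genes not past the test. In Model against Control, Cd274 (0.11) was -0.04 with tissue covariates and 0 (without Model 3) to 0.32 with 1 library left out. Mki67 (0.04) was -0.11 with tissue covariates, -0.01 with upper-quartile scaling, 0 with library size alone and -0.09 (without Model 3) to 0.19 with 1 left out, and Msln (0.46) was -0.04 (without Model 3) to 0.61. In LNPIFN-Y against Model, Mki67 (0.13) was -0.09 with tissue covariates, -0.08 without the libraries with no Zp3 count and -0.1 (without LNPIFN-Y 5) to 0.25 with 1 left out. In ptLNPIFN-Y against Model, Cbr2 (-2.15), a gene outside the naming rule, was -2.67 (without ptLNPIFN-Y 3) to 0.17 (without Model 2) with 1 left out. In ptLNPIFN-Y against LNPIFN-Y, without the libraries with no Zp3 count Ifng was 0.15 and Msln (-0.58) was 0.25. With 1 left out there, Ifng was -0.33 to 0.63 (without LNPIFN-Y 2), Msln -0.82 to 0.08 (without LNPIFN-Y 5) and Cxcl9 (0.15) -0.04 (without ptLNPIFN-Y 2) to 0.43.

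The correlation of the response with the change in the model, 0.574 for LNPIFN-Y and 0.517 for ptLNPIFN-Y, was 0.448 and 0.303 among genes above the median level, and 0.341 (without Model 1) to 0.625 and 0.34 (without Model 1) to 0.572 with 1 library left out. The correlation of the 2 particles' responses, 0.925, was 0.681 with the Model libraries split and 0.881 (without LNPIFN-Y 1) to 0.944 (without Model 3) with 1 left out.

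Depth limits the genes with few counts: Ifng had 4 counts over the Control and 10 over the Model libraries, and Cngb3 had 1 over the Model libraries.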

Other observations

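The genes in this part were chosen after their values were seen.

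Among macrophage and monocyte genes, Ly6c2, of inflammatory monocytes, rose by 4.17 ± 0.56 in LNPIFN-Y and 4.57 ± 0.57 in ptLNPIFN-Y against Model on the log2 scale (SE, n = 5 per group, edgeR adjusted p 6.85e-05 and 2.44e-05), and the Fc receptor Fcgr4 by 3.93 ± 0.58 and 3.97 ± 0.58 (0.000206 and 0.000161). Fcrls was at -1.5 ± 0.69 in LNPIFN-Y (0.249) and fell in ptLNPIFN-Y (-3.05 ± 0.73, 0.013), and the difference between the 2 particles did not pass for any gene. Without LNPIFN-Y 5, Fcrls was at -3.01 in LNPIFN-Y (0.00159), and without Model 3 Ly6c2 was at 4.76 and 5.2. With tissue covariates Fcrls was at -3.29 in LNPIFN-Y (0.00163) and -4.08 in ptLNPIFN-Y (8.38e-05), Fcgr4 at 3.2 in LNPIFN-Y and Ly6c2 at 3.86 in ptLNPIFN-Y.

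Cd209d, Ccl24 and Cbr2 were picked by hand and are no tested list. Cd209d had 26 counts over the Model libraries, 1 over LNPIFN-Y and 2 over ptLNPIFN-Y. That is 26-fold lower in LNPIFN-Y (95% counting interval 4.28 to 1070, edgeR adjusted p 0.00891), or at least 6.94-fold without LNPIFN-Y 3 (floor of 3 counts over the group). In ptLNPIFN-Y it was 12.9-fold lower (3.24 to 112, adjusted p 0.0203), or at least 6.85-fold without ptLNPIFN-Y 2, and the call was lost without Model 2 (0.065), ptLNPIFN-Y 4 (0.0548) or ptLNPIFN-Y 5 (0.0584) and with tissue covariates (0.0886). Ccl24 was at -2.58 ± 0.69 in LNPIFN-Y (0.0317; -3.2 and 0.013 with tissue covariates), lost with the replicate number as a block (0.0645) or without Model 1 (0.0612), Model 2 (0.062), Model 5 (0.0507), LNPIFN-Y 1 (0.0514), LNPIFN-Y 2 (0.0858) or LNPIFN-Y 5 (0.0678), and at -3.03 ± 0.72 in ptLNPIFN-Y (0.0124). Cbr2 was at -3.79 ± 1.07 in LNPIFN-Y (0.0408), lost with tissue covariates (-2.04, 0.414), with the replicate number as a block (-2.56, 0.27) or without Model 2 (-1.47, 0.367), Model 5 (0.0526), LNPIFN-Y 1 (0.0727), LNPIFN-Y 2 (0.102), LNPIFN-Y 3 (0.0605), LNPIFN-Y 4 (0.079) or LNPIFN-Y 5 (0.107), and was not past the test in ptLNPIFN-Y (-2.15 ± 0.99, 0.208; 0.17 without Model 2).

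Of 10 genes of the major urinary protein family, 7 were called higher in ptLNPIFN-Y than in Model. Mup15 (3.42, edgeR adjusted p 0.0514), Mup3 (1.97, 0.303) and Mup6 (-1.78, 0.301) were not, and none was called in LNPIFN-Y. Mup22 averaged 214 CPM in Control, 57.9 in Model, 352 in LNPIFN-Y and 1590 in ptLNPIFN-Y, with a log2 fold change of 4.78 in ptLNPIFN-Y against Model (edgeR adjusted p 0.0236). The call was lost without Model 1 (0.057), Model 4 (0.0665), Model 5 (0.0568) or ptLNPIFN-Y 5 (3.58, 0.0898), and the value was 5.68 without Model 2. With tissue covariates it was 4.02 (0.219), and with the replicate number as a block 4.53 (0.086). The adipocyte list had a median of 1.68 in the same comparison, with 0 members past the test over all genes and an adjusted p = 0.689 with an estimated correlation. Its call with the preset correlation was lost without Model 3 (0.0528), ptLNPIFN-Y 1 (0.0889) or ptLNPIFN-Y 5 (0.133). The family has similar copies, so the share of each copy is uncertain.

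No library was a copy of another of its group, and pairs across groups were not compared in this way. Over the 40 pairs within groups, the lowest chi-square per degree of freedom was 9.37, and Spearman correlations ran from 0.9427 to 0.9931. The first 3 principal components held 52.7%, 16.1% and 8% of the variance. Lists whose median, mean and test differ in sign were all far from passing, among them the adipocyte list in LNPIFN-Y against Model (median 0.52, mean 0.37, camera lower, adjusted p 0.895) and the mesothelial list in ptLNPIFN-Y against Model (-0.11, -0.11, camera higher, adjusted p 0.71).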
